A study of Mus musculus with 14 samples.

How the data were processed

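Mouse oocytes were collected at the germinal vesicle (GV) stage, in which the oocyte is arrested in the first meiotic prophase, and after ovulation. Per the labels, WT oocytes came from Mff fl/fl mice and CKO oocytes from Mff fl/fl mice with Gdf9-Cre, which expresses Cre recombinase in oocytes from early follicles on. There were 4 GV WT, 4 GV CKO, 3 ovulated WT and 3 ovulated CKO libraries, 14 in all. Per the labels' protocols, oocytes were lysed in cell lysis buffer and the first cDNA strand was made with SMART-SeqII, followed by PCR preamplification. The number of oocytes and of animals behind each library is not given in the sources used here, so p-values measure only the spread between these libraries.

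The authors deposited, for each stage, a table of read counts per gene and a table of FPKM. Per the file headers, the first holds a read count per gene and library; 17.6% of the GV and 18.3% of the ovulated values above 0 were not whole (tolerance 0.001), so they are estimated counts deposited without normalisation. Per the file headers, the second holds FPKM, fragments normalised to transcript length and mapped fragments, as deposited by the authors. Reads were aligned to mm10, per the submitters' processing notes; the aligner and the counting program are not given in the sources used here. The tables list only genes typed as mRNA, and 0 genes of the mitochondrial genome were among them.

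The GV table held 18194 genes and the table of ovulated oocytes held 16509, of which 16196 were in both. Of the 18507 gene identifiers in either table, 18456 matched the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, from which symbols of older lists and coordinates were taken. Library totals lay between 26575584 and 28847435 counts. Replicates differed by more than counting noise: over the 18 pairs of libraries within a group, chi-square per degree of freedom was 20.3 to 336, and Spearman correlation across genes with at least 20 counts in the pair was 0.95 to 0.985.

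Estimated counts were rounded to whole numbers. Each stage was fitted alone with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalisation, robust quasi-likelihood fit and F test), contrasting CKO with WT. The 4 groups were also fitted together on the genes in both tables, to test the change from GV to ovulated in each genotype and the difference of the genotype effect between stages (the interaction). P-values were adjusted with the Benjamini-Hochberg method over all genes of a comparison, and genes with adjusted p under 0.05 were called. Levels are TMM-normalised CPM, given as mean ± SD over libraries; fold changes are log2, with the standard error (SE) derived from the F statistic.

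Before the data were examined, 31 gene lists, the comparisons, the tests and the rule for named genes were fixed. Of these lists, 30 had at least 5 tested members. They were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists; camera compares a list with all other genes. Estimated correlations and fry, which asks whether a list's members move one way on balance, were alternatives. The camera tests of the lists from GV to ovulated in CKO were added after the data were seen. Markers of other cell types were summed per library as CPM of library totals, without TMM factors.

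The targeted gene was named first. Among called genes whose groups did not overlap and whose mean was at least 5 CPM in 1 group, the 8 largest rises and 8 largest falls were named, or 5 for the stage and interaction comparisons, without predicted gene models. For the interaction no overlap of groups is defined, and only the sign of the term was used. From each list past its test the 3 members with the smallest p in its direction were named, and from each other list up to 3 called members. Where fewer than 6 genes passed, the 6 with the smallest p were named. Genes named outside this rule are marked as chosen after their values were seen.

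The fits were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed, in 10 data sets per comparison. Of genes changed by a log2 fold of 1, the fit recovered on average 29.5% (19% to 40%) in the GV comparison (12044 to 12140 genes), 27.1% (21% to 31%) in the ovulated comparison (11707 to 11754 genes) and 2% (0% to 5%) in the interaction (12920 to 12949 genes). Of genes changed by a log2 fold of 2, it recovered 96.8% (94% to 99%), 93.7% (88% to 100%) and 51.8% (41% to 63%). False calls averaged 6.25%, 6.34% and 5.3% of the calls, at most 9.77%, 8.33% and 9.84%, and camera called 0 lists of these independent genes.

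Alternatives fixed beforehand were a log2 fold limit of 1, size factors by median of ratios (RLE), no filter, a mean of at least 10 CPM, the replicate number as a block, thinning to the smallest library, DESeq2 1.42.0, leaving out each library in turn, limma's voomWithQualityWeights, limma-trend on the deposited FPKM with pseudocounts of 1 and 0.1, and 1 fit over all 14 libraries. Alternatives chosen after seeing the data were fits without libraries that stood apart on the first principal component, a covariate for the share of counts in the 100 most abundant genes, and removal of each library's trend over transcript length and GC content (loess with span 0.5, GENCODE M21 transcripts). Other splits of the same libraries were refitted to count how often they gave as many calls. Library measures were compared with exact two-sided permutation tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.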

Results

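RNA was sequenced from mouse oocytes with and without an oocyte-specific deletion of Mff, which encodes the outer-membrane receptor that recruits the dynamin-related GTPase DRP1 to mitochondria for fission. GV oocytes gave 4 WT and 4 CKO libraries, and ovulated oocytes gave 3 WT and 3 CKO libraries. Library totals were 26575584 to 28847435 counts in the deposited tables of estimated counts, and values below are TMM-normalised CPM.

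The targeted gene, Mff (Entrez gene 75734, chromosome 1, 82724890 to 82752390 in GRCm38.p6), was far lower in every CKO library than in any WT library of its stage. In GV oocytes it measured 655 ± 209 CPM in WT (SD, n = 4) and 34.1 ± 6.20 CPM in CKO (SD, n = 4), a log2 fold change of -4.27 (SE 0.31, adjusted p = 0.000103). In ovulated oocytes it measured 523 ± 278 CPM in WT (SD, n = 3) and 52.8 ± 14.1 CPM in CKO (SD, n = 3), a log2 fold change of -3.31 (SE 0.36, adjusted p = 0.000155). The deleted part of the gene is not given in the sources used here, so the remaining reads can stem from the rest of the transcript. The per-library levels match the genotype labels in all 14 libraries.

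**Figure D1:**
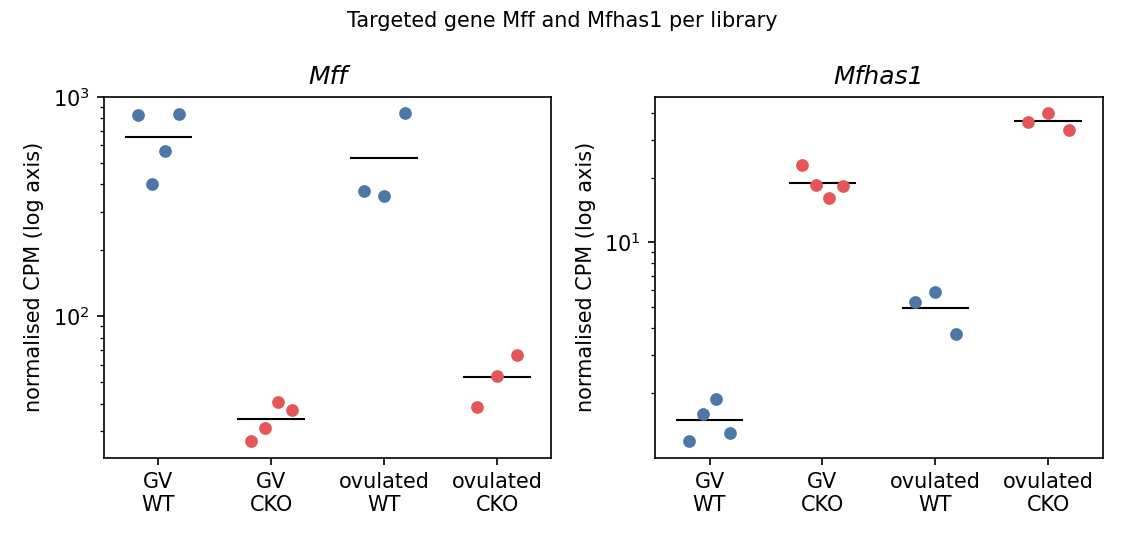
Normalised CPM of Mff and Mfhas1 on log axes, 1 point per library, with a line at each group's mean, for WT (blue) and CKO (red) oocytes of both stages. Mff lay between 27.0 and 66.7 CPM in the CKO libraries and between 355 and 844 CPM in the WT libraries, while Mfhas1 was higher in each CKO library than in every WT library.

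The GV comparison asks what loss of Mff changes in oocytes that have not resumed meiosis. Apart from Mff, 1 gene passed the test. Mfhas1 (Entrez gene 52065, chromosome 8, 35587789 to 35679449), a leucine-rich repeat protein with a GTPase-like domain, rose from 1.49 ± 0.309 CPM in WT to 19.0 ± 2.87 CPM in CKO (SD, n = 4 each), a log2 fold change of 3.66 (SE 0.25, adjusted p = 0.000103). Next by p-value, and not past the threshold, came Tmem254c (log2 fold change 2.02, adjusted p = 0.0722), Myo1e, a class I myosin (-1.61, adjusted p = 0.0735), Phlda2, an imprinted regulator of placental growth (1.46, adjusted p = 0.0735), and Hormad2, a protein of the meiotic chromosome axis (1.45, adjusted p = 0.126). In total 2 of 12298 tested genes were called, 1 higher and 1 lower. At an unadjusted p under 0.05 there were 820 genes, 404 higher and 416 lower, where 614.9 are expected by chance.

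Of the 30 tested lists, 5 passed camera in GV oocytes, with small median shifts and 0 called members. Nuclear-encoded subunits of the respiratory chain and ATP synthase (74 tested) had a median log2 fold change of 0.19 (adjusted p = 0.00914, and adjusted p = 0.966 with an estimated correlation), with Uqcrb at 0.55, Ndufa12 at 0.62 and Ndufa2 at 0.39. Mitochondrial ribosomal proteins (76 tested) had a median of 0.16 (adjusted p = 0.0132, and adjusted p = 0.966 with an estimated correlation), with Mrps33 at 0.59, Mrpl15 at 0.48 and Mrps18c at 0.59. Cytosolic ribosomal proteins (78 tested) also had a median of 0.16 (adjusted p = 0.00914, and adjusted p = 0.966 with an estimated correlation), with Rpl35a at 0.45, Rpl26 at 0.37 and Rps4x at 0.35. Markers of granulosa and cumulus cells, the somatic cells around the oocyte (21 tested), had a median of 0.58 (adjusted p = 0.0241, and adjusted p = 0.966 with an estimated correlation), with Col4a1 at 0.92, Inhbb at 1.11 and Inhba at 0.96, all at means of 0.281 to 2.12 CPM. Maternal-effect genes, whose products the early embryo needs (37 tested), had a median of -0.22 (adjusted p = 0.0227, and adjusted p = 0.966 with an estimated correlation), with Khdc3 at -1.32, Zar1 at -1.01 and Ago2 at -0.39.

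The other 25 lists did not pass in GV oocytes, among them mitochondrial fission and fusion (median log2 fold change -0.09) and the integrated stress response (-0.02). Adjusted over the list alone, 1 antioxidant gene, 2 early-embryo genes and 1 marker of blood, immune and stromal cells were higher. These members, named after their values were seen, were Gstp1, a glutathione transferase (log2 fold change 1.06), Zscan4d (1.03) and Zscan4c (1.11) of the 2-cell stage, and Cd68, a macrophage marker (1.82). Of the 8 GV libraries, 3 (WT 2, CKO 1 and CKO 2) stood apart on the first principal component, which held 43.8% of the variance. Their 100 most abundant genes took 38.1%, 35.2% and 42.4% of counts, against 48.2% to 51.1% in the other 5.

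Without those 3 libraries, an alternative chosen after seeing the data, 65 genes were called (33 higher, 32 lower), against 56 with DESeq2, 114 with limma's quality weights, 17 with the top-100 share as a covariate and 4 without a filter or in 1 fit over all libraries. The count was 1 on unfiltered log2 FPKM and 5 without WT 2. The lists past the threshold numbered 1 without WT 2, 0 without CKO 2, 1 without CKO 3, and 2 (maternal-effect genes and granulosa markers) with length and GC trends removed. They numbered 4 (2 shared) without the 3 libraries and 6, 0 of them downward, with the covariate. Without the 3 libraries the respiratory chain, mitochondrial ribosome and granulosa calls were lost (camera adjusted p = 0.142, 0.145 and 0.656). The maternal-effect call was lost with the covariate (adjusted p = 0.506) and without WT 1, WT 4, CKO 1 or CKO 2 (adjusted p = 0.149, 0.122, 0.488 and 0.0843). The granulosa call was lost with the covariate (adjusted p = 0.201) and without WT 2, WT 3, CKO 1, CKO 2 or CKO 3 (adjusted p = 0.0754, 0.311, 0.13, 0.322 and 0.166). The respiratory chain, mitochondrial ribosome and cytosolic ribosome calls were lost without WT 2 (adjusted p = 0.0754, 0.108 and 0.535), CKO 2 (adjusted p = 0.322, 0.466 and 0.322) or CKO 3 (adjusted p = 0.166, 0.166 and 0.494).

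In ovulated oocytes the question is what Mff loss changes once meiosis has resumed. The most called genes of any list were 48 of 74 respiratory chain subunits and 44 of 78 cytosolic ribosomal proteins, all higher in CKO oocytes. Chchd2, a protein of the mitochondrial intermembrane space (Entrez gene 14004, chromosome 5, 129881161 to 129887470), rose from 8.41 ± 3.36 CPM in WT to 190 ± 126 CPM in CKO (SD, n = 3 each), a log2 fold change of 4.50 (SE 0.46, adjusted p = 0.000124). Cox7c, a subunit of cytochrome c oxidase, rose from 5.27 ± 2.67 to 105 ± 34.0 CPM (4.31, SE 0.41, adjusted p = 6.84e-05). Figla, a transcription factor of early oocytes that drives zona pellucida genes, rose from 0.826 ± 0.263 to 13.9 ± 7.74 CPM (4.06, SE 0.50, adjusted p = 0.000309).

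The other largest rises were of Snrnp25, a protein of the minor spliceosome (4.62), Pet100, an assembly factor of cytochrome c oxidase (4.32), Hint1, a nucleotide hydrolase (4.19), Mrpl33 of the mitochondrial ribosome (4.15) and Phpt1, a protein histidine phosphatase (4.03). Mfhas1, called in GV oocytes and named here after its value was seen, rose too, from 4.98 ± 1.10 to 36.5 ± 3.26 CPM (2.87, adjusted p = 0.000186). The largest falls were of Chst5, a sulfotransferase, from 9.68 ± 3.63 to 1.25 ± 0.511 CPM (-2.95, adjusted p = 0.00178), Mdga2 (-2.73), Nyap2 (-2.56), Lrmp (-2.47), Bbx, an HMG-box protein (-2.31), Slco4c1, an organic anion transporter (-2.22), Fstl5 (-2.19) and the transcription factor Sox6 (-2.14). In total 942 of 12010 tested genes were called, 774 higher and 168 lower, or 82.2% higher. Groups did not overlap in 918 of these genes, and in 28.5% of all tested genes, where chance gives 10% for 3 against 3. Gene models known only by a systematic name made up 39 of the calls.

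**Figure D2:**
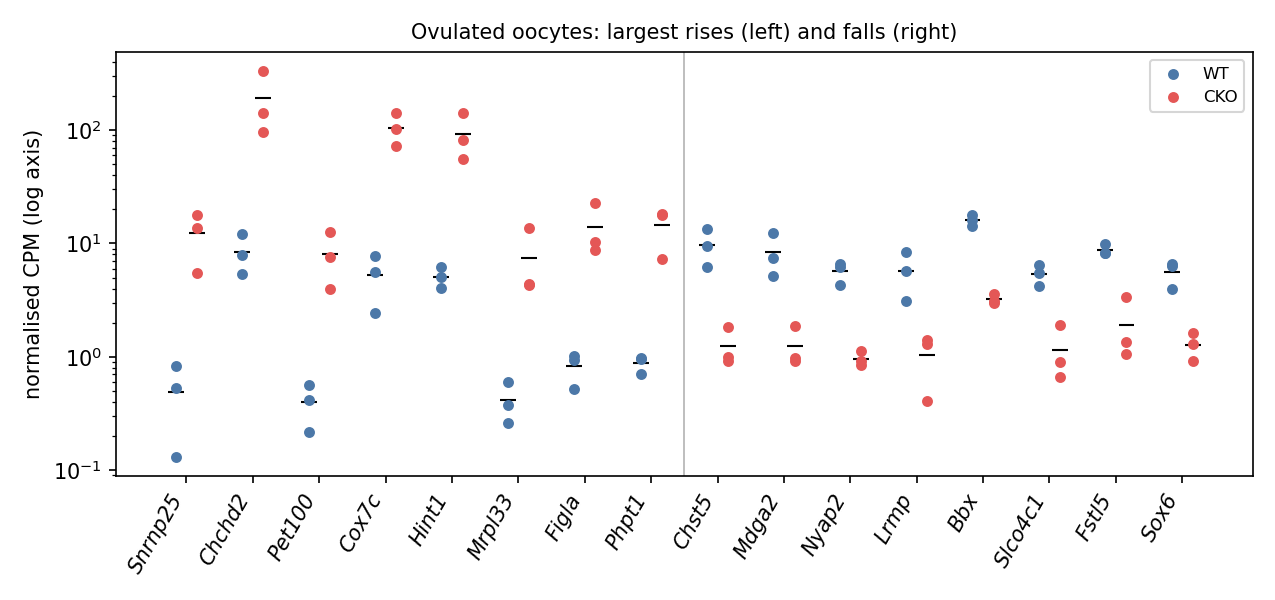
Normalised CPM on a log axis of the 8 genes with the largest rise and the 8 with the largest fall in ovulated CKO oocytes, 1 point per library and a line at each group mean, for WT (blue, n = 3) and CKO (red, n = 3). In each of the 16 genes the CKO libraries lay wholly above or wholly below the WT libraries.

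Of 74 respiratory chain subunits tested in ovulated oocytes, 48 rose and 0 fell, with a median log2 fold change of 1.67 (camera adjusted p = 1.65e-32, and adjusted p = 0.864 with an estimated correlation). Beside Cox7c, Uqcrh of complex III rose by 2.67 and Atp5j of ATP synthase by 3.27. Of 78 cytosolic ribosomal proteins, 44 rose and 0 fell, with a median of 1.65 (adjusted p = 9.57e-29, and adjusted p = 0.864 with an estimated correlation), such as Rpl5 (2.68), Rps29 (2.84) and Rps13 (3.29). Of 76 mitochondrial ribosomal proteins, 14 rose and 0 fell, with a median of 0.72 (adjusted p = 7.72e-05, and adjusted p = 0.975 with an estimated correlation), with Mrpl30 at 2.59 and Mrpl28 at 2.69 beside Mrpl33.

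Among 34 antioxidant genes, 7 rose and 1 fell, with a median of 0.64 (adjusted p = 0.00633, and adjusted p = 0.864 with an estimated correlation). The mitochondrial glutaredoxin Glrx5 (2.64), superoxide dismutase Sod1 (2.05) and peroxiredoxin Prdx5 (1.92) rose, and the secreted glutathione peroxidase Gpx3, named after its value was seen, fell (-1.13, adjusted p = 0.034). Of 36 proteasome subunits, 6 rose and 0 fell, with a median of 0.33 (adjusted p = 0.00688, and adjusted p = 0.864 with an estimated correlation), including the catalytic subunits Psmb7 (4.01) and Psmb5 (2.79) and the structural subunit Psmb4 (3.08). Of 34 genes of oocyte identity, 7 rose and 0 fell, with a median of 0.06 (adjusted p = 0.0392, and adjusted p = 0.864 with an estimated correlation), including Figla, E330017A01Rik (3.54) and the zona pellucida gene Zp2, which rose from 147 ± 25.6 to 742 ± 195 CPM (2.33). Adjusted over the list alone, 57 respiratory subunits, 56 cytosolic and 18 mitochondrial ribosomal proteins, 10 antioxidant, 8 proteasome and 9 oocyte identity genes were higher, and 1, 0, 1, 2, 1 and 0 were lower.

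**Figure D3:**
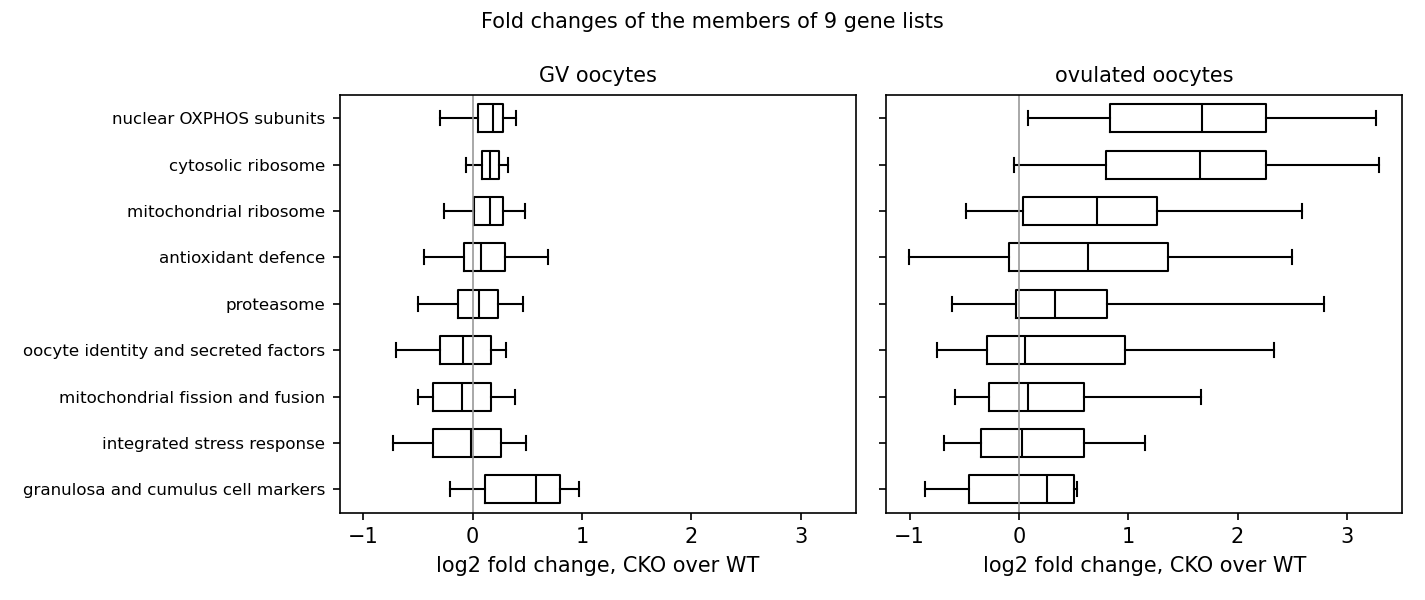
Log2 fold changes (CKO over WT) of the tested members of 9 gene lists in GV and ovulated oocytes, on a shared axis, with boxes from the first to the third quartile, a line at the median and whiskers at percentiles 5 and 95. The medians of the respiratory chain and cytosolic ribosome lists were 0.19 and 0.16 in GV oocytes and 1.67 and 1.65 in ovulated oocytes.

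The remaining 24 lists did not pass in ovulated oocytes, although most held called members. In mitochondrial fission and fusion, 2 of 33 rose, Fis1, another outer-membrane fission factor (2.29), and Mtfr1l (1.96). In mitochondrial transport, 3 of 19 rose, the docking protein Snph (3.22), Mtx2 of the outer-membrane sorting machinery (1.88) and the dynein light chain Dynll1 (1.61). In mitochondrial DNA maintenance and expression, the RNA-binding Slirp rose (2.65) and Mterf1a fell (-1.21). In the tricarboxylic acid cycle and fatty acid oxidation, 4 of 35 rose, among them Dlst (1.87) and Sdhb (1.49). Calcium handling had 3 rises and 1 fall of 35, with calmodulin Calm2 (1.86), the uniporter regulator Smdt1 (2.59) and the outer-membrane channel Vdac2 (-1.31). Lonp2 of peroxisomes (1.37) and Fdft1 of sterol synthesis (2.27) each rose alone in their lists.

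Stress lists were mixed. The integrated stress response had Atf4 up (1.56) and Ppp1r15a down (-0.88), while the endoplasmic reticulum list had Derl3 up (3.14) and Edem2 down (-1.01). Autophagy had Map1lc3a (2.91) and the mitophagy receptor Bnip3l (0.88) up and Becn1 down (-0.90). Apoptosis had Birc5 (1.88) and Mcl1 (1.81) up and Htra2 down (-0.98). The heat shock list had Dnaja1 up (1.66) and Hsp90ab1 down (-0.92), and the DNA damage list had Topbp1 up (1.97).

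In the meiotic cell cycle, 4 of 41 rose, with the anaphase-promoting complex activator Fzr1 (2.24), the phosphatase Cdc25b (2.31) and the kinase Wee1 (2.09). In the spindle list, 2 of 43 rose, the meiotic cohesin Stag3 (4.08, from 0.138 ± 0.132 to 2.45 ± 1.64 CPM) and Haus1 (1.24). In the actin list, 3 of 33 rose, Actg1 (1.36), Actb (1.03) and Cfl1 (1.20). Of 39 maternal-effect genes 6 rose, with Khdc3 (2.58) and Padi6 (1.58) of the subcortical complex and Uchl1 (1.70). Tob1 (2.58) and Ybx2 (1.99) rose among 61 regulators of maternal mRNA, Kmt2a (4.35, from 0.144 ± 0.0395 to 3.03 ± 0.939 CPM) and Dnmt3l (1.10) among 54 chromatin genes, and Arg2 (2.54), Zscan4c (1.56) and Dppa4 (2.38) among 20 early-embryo genes. Glycolysis, innate immunity, and the markers of granulosa and of blood, immune and stromal cells had 0 called members. The 13 mRNAs of the mitochondrial genome could not be tested in any comparison, since the tables do not list them.

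The ovulated count moved with single libraries: it was 514, 567 and 453 without WT 1, 2 and 3, 1647 without CKO 1 and 331 without CKO 2. It was 235 without WT 3 and CKO 2, the pair farthest out on the first principal component, a choice made after seeing the data. With length and GC trends removed it was 812 (527 higher, 285 lower, 64.9% higher; 629 shared). Then 2 lists were past the threshold, respiratory chain (adjusted p = 3.3e-10) and cytosolic ribosome (adjusted p = 2.54e-06). Without WT 2 there were 3 lists. The oocyte identity call was lost without WT 1, WT 2, CKO 1 or CKO 3 (adjusted p = 0.0743, 0.209, 0.0678 and 0.0574), and the antioxidant and proteasome calls without WT 2 (adjusted p = 0.0619 each).

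Whether the genotype effect itself differed between the stages was tested as an interaction, and 430 of 13199 genes passed, 419 with a more positive CKO effect in ovulated oocytes and 11 with a more negative one. Cox7c measured 98.9 ± 10.8 CPM in WT and 121 ± 27.9 CPM in CKO GV oocytes (SD, n = 4 each) and 4.41 ± 2.24 CPM in WT and 85.3 ± 27.7 CPM in CKO ovulated oocytes (SD, n = 3 each), a log2 difference of 3.98 (SE 0.47, adjusted p = 0.000474). Zp2 measured 123 ± 23.1 CPM in ovulated WT and 604 ± 159 CPM in ovulated CKO oocytes, from 4354 ± 1321 and 3856 ± 1441 CPM in GV oocytes (2.47, adjusted p = 0.0121). Of 74 respiratory subunits 26 passed, all more positive in ovulated oocytes, as did 29 of 78 cytosolic ribosomal proteins, 8 of 77 mitochondrial ribosomal proteins, 5 of 34 oocyte identity genes, 4 of 37 antioxidant genes and 3 of 37 proteasome subunits.

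These were the 6 lists past the threshold, with medians of 1.34 (adjusted p = 6.47e-28), 1.33 (adjusted p = 5.54e-25), 0.50 (adjusted p = 0.00255), 0.06 (adjusted p = 0.0165), 0.43 (adjusted p = 0.0303) and 0.37 (adjusted p = 0.0093). Each had an adjusted p = 0.762 with an estimated correlation. For Mff the difference was 0.91 (adjusted p = 0.358). The count was 239, 227 and 231 without GV WT 1, 3 and 4, 269 and 224 without ovulated WT 1 and 2, and 1006 and 129 without ovulated CKO 1 and 2. It was 883 with DESeq2 and 229 without the 3 GV libraries that stood apart, an alternative chosen after seeing the data. The lists numbered 3 without GV CKO 1 and 2 with length and GC trends removed. The antioxidant call was lost in 7 fits without 1 library (GV WT 1, WT 4 and CKO 1, ovulated WT 1, WT 2, CKO 2 and CKO 3; adjusted p = 0.0558 to 0.23). The oocyte identity call was lost in 5 (GV WT 1, WT 4 and CKO 1, ovulated WT 2 and CKO 3; adjusted p = 0.0524 to 0.174) and the proteasome call without GV CKO 1 (adjusted p = 0.121).

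Over 11440 genes tested in both stages, Spearman's rho between their fold changes was 0.274 and Pearson's r 0.27; genes are not independent replicates, and the stages share no library. Mfhas1 was the 1 gene called higher in both, and Mff, the deleted gene, the 1 called lower in both. Of 768 genes that rose in ovulated CKO oocytes, 565 had a positive fold change in GV oocytes (median 0.17), and of 163 that fell, 16 did (median -0.46).

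The course from GV to ovulated oocytes in WT gives the background for these differences. Upp1, uridine phosphorylase, went from 579 ± 141 CPM (SD, n = 4) to 1.23 ± 0.594 CPM (SD, n = 3), a log2 fold change of -8.88 (adjusted p = 8.84e-09), and Cpsf4l, a relative of a polyadenylation factor, fell by 8.59. Mtg2, Tuba1a and Iqcf1 fell to 0.0104, 0.0326 and 0.0345 CPM, too near 0 counts for a fold. The largest rises were of the transcription factor Insm1 (4.45), the kinase Pim1 (4.27), the mTOR inhibitor Ddit4 (3.94), Ubqln2 (3.80) and Rpia, an enzyme of the pentose phosphate pathway (3.75). CPM are relative to the counts of each library. A rise or fall between stages is thus one of relative level and need not mean more or less mRNA per oocyte, nor new transcription.

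Of 78 cytosolic ribosomal proteins 72 fell and 0 rose in WT (median -3.71, adjusted p = 1.18e-27, and adjusted p = 0.347 with an estimated correlation), including Rpl19 (-6.17) and Rpl24 (-7.18). Of 74 respiratory subunits 59 fell and 2 rose (median -2.73, adjusted p = 2.13e-15, and adjusted p = 0.347 with an estimated correlation), including Cox4i1 (-5.91), Ndufs7 (-6.03) and Atp5g1 (-4.94). Mitochondrial ribosomal proteins (60 fell, 4 rose, adjusted p = 3.45e-12; Mrpl46, -4.78), proteasome subunits (27 fell, 3 rose, adjusted p = 1.29e-06; Psmc2, -5.64), antioxidant genes (22 fell, 6 rose, adjusted p = 0.00728; Gpx4, -5.88), the tricarboxylic acid cycle list (23 fell, 7 rose, adjusted p = 0.0282; Mdh2, -5.68) and oocyte identity genes (16 fell, 5 rose, adjusted p = 0.0491; Zp3, -4.51) passed downward. With an estimated correlation these lists had adjusted p = 0.347 to 0.805. Chromatin genes (35 rose, 5 fell, adjusted p = 2.85e-05; Kdm6b, 1.77), regulators of maternal mRNA (32 rose, 15 fell, adjusted p = 0.00225; Upf1, 3.01) and actin genes (16 rose, 6 fell, adjusted p = 0.0491; Ect2, 1.82) passed upward, each with adjusted p = 0.347 with an estimated correlation. The actin and oocyte identity calls were lost in 8 and 9 of the 14 fits without 1 library (adjusted p = 0.05 to 0.0605 and 0.0521 to 0.0675). With the replicate number as a block, the tricarboxylic acid cycle, actin and oocyte identity calls were lost (camera adjusted p = 0.0554, 0.11 and 0.11). RLE size factors also lost the oocyte identity call (camera adjusted p = 0.0513).

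In CKO oocytes the same respiratory list had 44 falls and 5 rises from GV to ovulated (median -1.23, adjusted p = 3.14e-06, and adjusted p = 0.646 with an estimated correlation), and the cytosolic ribosome list 67 falls and 2 rises (median -2.39, adjusted p = 6.85e-21, and adjusted p = 0.439 with an estimated correlation), both tested after the data were seen. Upp1 fell by 6.18 and Tuba1a to 0.0933 CPM, while Rpgrip1 (4.30), Ddit4 (4.19), Pim1 (4.03), Rpia (3.52) and the microtubule-binding Clasp2 (3.25) rose. The granulosa markers Hsd3b1 and Gja1 fell to 0.01 and 0 CPM from 26.7 ± 19.1 and 5.60 ± 3.80 CPM, and Aldh1a1 to 0.072 CPM. Of 21 granulosa and cumulus markers 9 fell and 5 rose in CKO, and the list did not pass (adjusted p = 0.552). In total 8772 of 13199 genes were called in WT (3997 higher, 4775 lower) and 7183 in CKO (3060 higher, 4123 lower), and Mff changed by -0.79 in WT (adjusted p = 0.042) and 0.12 in CKO (adjusted p = 0.775). Each stage has its own deposited table, so stage and any batch between the tables cannot be told apart.

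Library complexity and marker sums were compared within stages, on CPM of library totals without TMM factors. In ovulated oocytes 10071 ± 66.6 genes reached 1 CPM in WT and 10646 ± 343 in CKO (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows), and 13946 ± 307 and 14365 ± 330 genes had at least 1 count (exact permutation p = 0.2). In GV oocytes 15625 ± 250 and 15830 ± 194 genes had at least 1 count (exact permutation p = 0.257). Summed granulosa and cumulus markers were 101 ± 30.2 CPM in WT and 128 ± 48.6 CPM in CKO GV oocytes (exact permutation p = 0.371) and 134 ± 4.78 and 124 ± 10.8 CPM in ovulated oocytes (exact permutation p = 0.3). Without Cyp19a1, the most abundant marker, the ovulated sum was 1.27 times as high in CKO as in WT, with every CKO library above every WT library; with TMM factors it was 1.11 times as high and the libraries overlapped. Markers of blood, immune and stromal cells were 82.3 ± 29 and 89.1 ± 18.5 CPM in GV oocytes (exact permutation p = 0.543) and 129 ± 31.3 and 92.8 ± 24.1 CPM in ovulated oocytes (exact permutation p = 0.2).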

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

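The tests of granulosa and cumulus RNA below, for the ovulated pattern and for the GV libraries, and the test of library depth were chosen after their values were seen, as were the fits without single groups of libraries and with length and GC trends removed.

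The effect of genotype differed between the stages, by the interaction term, for 430 genes and, with a preset correlation, for 6 gene lists, each with adjusted p = 0.762 with an estimated correlation. Among named genes the log2 difference (ovulated minus GV) was 3.98 for Cox7c, 3.48 for Ndufc1 and 2.90 for Atp5j of the respiratory chain, 3.71 for Mrpl33, 2.41 for Mrpl30 and 3.57 for Mrpl43 of the mitochondrial ribosome, and 3.20 for Rpl7, 2.50 for Rpl5 and 2.90 for Rps27 of the cytosolic ribosome. It was 2.41 for Gpx4, 1.81 for Prdx5 and 2.58 for Glrx5 of antioxidant defence, 3.95 for Figla, 3.27 for E330017A01Rik and 2.47 for Zp2 of oocyte identity, and 3.83 for Psmb7, 2.29 for Psmb5 and 3.06 for Psmb4 of the proteasome. The largest were 5.76 for Acy3, 5.36 for Best2, 5.34 for Mtg2, 5.26 for Snx15 and 4.95 for Commd4, whose means in ovulated WT oocytes were 0.0226, 0.0418, 0.0104, 0.0986 and 0.0729 CPM, so these fitted values are no bounds. Magea5 had the most negative difference, -2.21. Genotype names were moved within each stage, and 100 splits were drawn from 700, the real one included. Of these, 8 called at least as many genes as the real 430 (highest other 1243). At least as many lists as the real 6 were called in 21 (highest other 11), so chance cannot be excluded for the lists. All 7 of the other splits with as many genes kept the real groups of the ovulated libraries and moved only GV libraries. They thus kept the ovulated genotype difference within the tested term, so the splits cannot decide whether the gene count is due to chance. Of these 7, the split with 1243 genes exchanged WT and CKO in all GV libraries. It kept the real groups of both stages and tested the sum of their genotype effects, so it is no random regrouping. The splits that broke up the ovulated groups called at most 3 genes.

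GV WT 2 lay far from the other GV WT libraries in summed markers of blood, immune and stromal cells, at 125.3 CPM against 74.45 CPM in the nearest. It was the 1 outlying value among 56 groups of 4 libraries tested, where chance gives about 2.8.

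The first pattern weighed is the higher level of respiratory chain and cytosolic ribosome mRNAs in ovulated CKO oocytes. Length and GC bias between libraries was argued against as the whole cause, because 0% of 10000 random lists matched on length, GC content and expression reached the median of 1.66 (highest 0.957), although the matched lists themselves had a median of 0.488. RNA of granulosa or cumulus cells was argued against as the whole cause, since it would raise their markers at least as much, yet the 11 tested markers had a median of 0.261 (SD 0.603, highest 0.551), and the 19 too low to test summed to 2.22 ± 1.41 CPM in WT and 1.29 ± 0.688 CPM in CKO (SD, n = 3 each), although all markers without Cyp19a1 summed to 1.27 times the WT level in CKO (1.11 times with TMM factors). A candidate explanation is that ovulated CKO oocytes had gone less far from the GV state. An axis from GV WT (0) to ovulated WT (1) was built on 13046 genes outside both lists. On it the CKO libraries lay at 0.587, 0.782 and at most 0.849, and the WT libraries, each placed on an axis made without it, at 0.913 to 1. The 13046 genes include other genes called in these same CKO libraries, so the positions partly restate the pattern and are no independent support. Distance off the axis was not measured, so a position below 1 does not show that a library lies between the GV and ovulated WT states. Genes called in ovulated oocytes also differed by genotype in GV oocytes, as given below, which a shorter course from the GV state would not by itself give. What stays open is whether Mff loss, the Cre that all CKO oocytes carry, the time of collection or poly(A) tail length, on which cDNA priming can depend, lies behind it, and none of these was tested. Library complexity stays open too. The ovulated CKO libraries had 10423, 11041 and 10475 genes at 1 CPM, and the WT libraries 10148, 10028 and 10038. Numbers of genes with at least 1 count overlapped between the genotypes. Whether complexity is a cause or a result of the pattern was not tested.

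The second pattern is the rise of Mfhas1 in CKO oocytes of both stages, by 3.66 and 2.87 on the log2 scale. An inserted sequence, such as a transgene, may act on genes near its site, yet 0 of 6 neighbours within 1 Mb that were tested in both stages passed in both; an insertion can act on 1 gene alone, so this cannot be told apart from an effect of Mff loss. Reads shared with another gene stay open as well, as 1.28% of the 50-base windows of Mfhas1 transcripts occur in another gene, Gm16793, above the bound of 1% set beforehand for setting this aside. The place of the Cre transgene is not given in the sources used here, and no CKO library lacks Cre.

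The last pattern is that 3 GV libraries, from both genotypes, stood apart. Length and GC bias was argued against, since with each library's trends removed the 3 libraries still lay beyond the other 5, with a gap of 35.2 on the first principal component. Library depth stays open, since the mean total of the 3 libraries was 0.973 times that of the other 5, a difference above the SD of the other 5, though the total of CKO 1 lay within their range. RNA of granulosa cells stays open: as CPM of library totals, summed markers in the lowest of the 3 libraries lay 12.2 CPM above the highest of the other 5, but 49 CPM below it with TMM factors and 10.8 CPM below it without Cyp19a1. The design gives no group that follows this split; differences in handling or in maturity stay open, and on the axis toward the ovulated state the 3 libraries lay at 0.0354, 0.0934 and 0.149, the other 5 at -0.0531 to 0.00246.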

How the results depend on the processing

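Fits without the 3 GV libraries that stood apart or without ovulated WT 3 and CKO 2, the top-100 covariate and the removal of length and GC trends were chosen after seeing the data. Mff kept its direction and stayed past the threshold in both stages under each alternative, except in ovulated oocytes on unfiltered log2 FPKM (-2.99, adjusted p = 0.063), where more genes were tested. Of 6912 values of named genes under the alternatives, 6502 kept direction and side of the threshold, 385 dropped below it, 22 came past it and 3 reversed, all of Mff from GV to ovulated in CKO, which was not called: -0.338 with the replicate block, -0.0879 without ovulated CKO 3 and -0.0777 without the 3 GV libraries. Most drops were in the ovulated comparison (248, against 1177 unchanged) and the interaction (123, against 812 unchanged). The courses from GV to ovulated had 6 drops in WT (2078 unchanged) and 7 in CKO (2031 unchanged), and the GV comparison had 1 (404 unchanged).

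Counts of genes moved by over 1.5 times as follows; the cause was not tested unless given. GV oocytes gave 4 without a filter, 4 in 1 fit over all libraries, 56 with DESeq2, 114 with voomWithQualityWeights, 65 without the 3 libraries, 17 with the covariate, 1 on unfiltered log2 FPKM, and 2 to 5 when leaving out each library. Ovulated oocytes gave 506 at a mean of at least 10 CPM (fewer genes tested; 490 shared), 1602 with DESeq2, 1953 with voomWithQualityWeights, 1595 in 1 fit over all libraries, 235 without WT 3 and CKO 2, 13 on unfiltered log2 FPKM, and 331 to 1647 when leaving out each library. The interaction gave 883 with DESeq2, 229 without the 3 GV libraries and 129 to 1006 when leaving out each library. The course from GV to ovulated gave 5155 genes in WT and 4458 in CKO at 10 CPM. The main fits had, as fixed beforehand, no block for the replicate number. Same-numbered WT and CKO libraries correlated at -0.503 to 0.592 in GV and 0.0581 to 0.366 in ovulated oocytes, not all above 0.1. In GV oocytes 3 of 8 and in ovulated oocytes 5 of 6 libraries correlated best with their own number. Pairing by replicate number thus cannot be excluded in ovulated oocytes. With the numbers as a block the counts were 2 (GV), 1630 (ovulated), 262 (interaction), 6956 (WT course) and 4663 (CKO course).

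Lists past the threshold fell to 0 with an estimated correlation in each comparison. With fry they were 0 in GV oocytes, ovulated oocytes and the interaction and 21 in the WT course. With length and GC trends removed they were 2 in GV oocytes, 2 in ovulated oocytes and 2 for the interaction. Leaving out each library gave 0 to 7, 3 to 6 and 3 to 7. Spearman's rho between stages was 0.31 at 10 CPM, 0.30 for ratios of mean CPM and 0.204 to 0.368 when leaving out each library. The remaining alternatives (log2 fold limit, RLE, thinning, filtered log2 FPKM) left the counts within 1.5 times. The permutation tests of library complexity kept their verdict under their own alternatives, but in ovulated oocytes no p under 0.1 was possible. Results that moved with the top-100 share as a covariate are given above.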

Other observations

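The lists in the next paragraph were chosen after the ovulated results were seen; the score and the splits that follow were set out before their results were seen.

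Subunits of other complexes, large ones such as Polr2a included, were tested because Snrnp25, Chchd2 and Pet100 pointed beyond the fixed lists. These 3 genes were left out of the lists. Of 23 proteins of mitochondrial import 8 rose and 0 fell, with a median log2 fold change of 1.12 (camera adjusted p = 2.02e-05 over 3 lists, and adjusted p = 0.264 with an estimated correlation). Of random lists matched on length, GC content and expression, 0.03% reached that median. Among the members were Tomm6 of the outer-membrane translocase, from 12.3 ± 3.00 to 82.7 ± 38.4 CPM (2.75), the chaperone Timm9 (2.40) and the pore protein Tomm40 (3.37, at 0.694 ± 0.355 CPM in WT). Of 26 RNA polymerase subunits 5 rose and 0 fell, with a median of 0.515 (adjusted p = 0.000556, and adjusted p = 0.264 with an estimated correlation), among them Polr1d (2.04) and Polr2l (1.54), and 1.14% of matched lists reached it. Of 23 spliceosomal Sm and LSm proteins and relatives 4 rose, among them Lsm4 (3.30) and Snrpd2 (2.32), and 0 fell, with a median of 0.0844 (adjusted p = 0.0458, and adjusted p = 0.537 with an estimated correlation). That median is no higher than matched genes give, as 57.7% of matched lists reached it, so 2 of the 3 lists stood above their matched lists.

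The second hypothesis was that part of the ovulated difference is already present in GV oocytes. Each GV library was scored on the 929 genes called in ovulated oocytes and tested in GV oocytes, without Mff and Mfhas1, as the mean log2 CPM of the genes that rose minus that of the genes that fell. The score was 1.01 ± 0.119 in WT and 1.69 ± 0.142 in CKO oocytes (SD, n = 4 each), with each CKO library above every WT library (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows; adjusted 0.0286 over 3 relations). The genes that rose went from 5.06 ± 0.0646 to 5.22 ± 0.0486, and those that fell from 4.05 ± 0.153 to 3.53 ± 0.181, each with the same exact p, and 146 of the 162 genes that fell had a negative fold change in GV oocytes. The genes were chosen on ovulated libraries alone, so a weak form of the difference may precede ovulation, but Mff loss and Cre cannot be separated here either. The score was not corrected for trends over length and GC content. With those trends removed, the GV calls of the respiratory chain, mitochondrial ribosome and cytosolic ribosome were lost (camera adjusted p = 0.771, 0.151 and 0.448). Such a bias thus stays open for the score.

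Other splits of the same libraries were refitted to ask whether a random grouping of libraries gives as many calls. Of the 35 splits of the GV libraries, 4 called at least as many genes as the real 2. At least as many lists as the real 5 were called in 20 (highest other 13), so chance cannot be excluded for either count. These counts do not judge the 2 genes themselves. Mff was deleted by design, and Mfhas1 was called higher again in ovulated oocytes. The highest other split called 876 genes and set the 3 libraries that stood apart, with CKO 3, against the rest, which points to a structure of the samples other than genotype. The 10 splits of the ovulated libraries are too few for a share under 0.05: the real split called 942 genes, the highest other 1, and 6 lists, the highest other also 6, with 1 and 2 splits reaching the real value. For the course from GV to ovulated oocytes, 1 of 35 splits reached the real 8772 genes in WT (highest other 4455). In CKO 1 of 35 reached the real 7183 (highest other 5113). In both that 1 is the real split. The highest other split exchanged the stage names but still grouped the libraries by stage, except GV WT 2 in WT and GV CKO 1 in CKO. The share is the smallest that 35 splits allow and lies under 0.05, which argues against chance but does not exclude it. Stage and any batch between the tables cannot be told apart by these splits. For the lists, 7 of 35 reached the real 10 in WT (highest other 11), so chance cannot be excluded for them.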
